A study of Mus musculus with 8 samples.

How the data were processed

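Kidneys of wild-type C57BL/6 mice, described as male and 60 days old in the labels, were compared 24 h after unilateral ureteral obstruction (UUO), in which the ureter of the left kidney is blocked and urine backs up into it. The unobstructed right kidney served as the control (CTRL). There were 4 UUO and 4 CTRL libraries. The labels name 4 mice, so each mouse gave both kidneys, but they do not say which kidneys share a mouse. The kidney numbers in the titles are not shared between the groups and differ by a constant 21 when taken in order. The p-values therefore treat the 8 kidneys as independent. Total RNA was extracted with the miRNeasy kit, libraries were made with the Ovation Universal RNA-Seq System, and paired reads of 100 nt were sequenced to 50 M pairs per library, per the labels.

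The authors deposited 1 table with 48526 Ensembl genes and 1 column per library. The authors' deposited values are a signal in normalised reads, made as gene counts divided by 1 size factor per library, with no scaling by gene length or to a common library total. This was read from the deposited values, all of which (100%) were whole multiples of the value of 1 read in their column within a tolerance of 0.001 read. HISAT2, HTSeq and DESeq2 were named without versions in the submitters' processing notes, together with build GRCm38.p6. The annotation release and the strand setting of the counting were not given in the sources used here. Reads of genes that overlap on opposite strands therefore cannot be taken as told apart, and genes with near-identical copies are uncertain.

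Whole reads were recovered by dividing each column by the value of 1 read. The totals ran from 17.9 to 25.0 M reads per library, and 29330 genes had a read in at least 1 library. A gene with no read in a library was given a floor of 3 reads, which covers counting error only, and the same holds for every counting interval. Symbols were found for 48058 gene identifiers and not for 468. Coordinates, biotypes and exon overlaps came from a GENCODE annotation of the same build (GRCm38).

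The design written before the data were examined named limma for normalised values and edgeR for counts. As the table holds normalised values, limma 3.58.1 with a mean-variance trend was fitted to log2(value + 1) with no further scaling, and fold changes are on that scale, which understates the change of genes with few reads. Genes with a value of at least 10 in at least 4 of the 8 libraries were kept, which left 16669 genes and 99.9% of the reads. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. In all, 29 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way and compares them with no other genes. R 4.3.3, Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used. Values given as mean ± SD have n = 4 kidneys per group.

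The genes named were set by a rule written beforehand. It took Hnf1b, Hnf1a and Hnf4a, and the members of the HNF1B-dependent list. It added the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean value of at least 100 and no overlap between groups, predicted genes and pseudogenes left out. From each list it took the 4 members with the smallest p, and, where members divided, the member on the minority side with the smallest p. Lcn2 falls outside the rule and was chosen after its values were seen.

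The alternatives were pseudocounts of 0.5 and 8, no filter and a minimum mean of 50, rescaling to a median ratio of 0 on the log2 scale, by TMM and to equal sums, robust variances, sample quality weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, an estimated correlation, lists without shared members, and each library left out in turn. After the data were seen, leaving out CTRL sample 4 and UUO sample 4 together, and leaving Hnf4a and proximal tubule members out of the HNF1B-dependent list, were added, as was a block on the title numbers paired by their constant difference.

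The tests were tested on simulated data drawn from the means and depths of these libraries for 16669 genes. For UUO against CTRL, limma recovered 60% of genes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 5.38% of its calls were unchanged genes. That share was 5.88% for edgeR and 15.8% for DESeq2. Only a small part of the genes was changed in the simulation, equally up and down. In the real data 59.6% of the genes passed the threshold, so these shares need not hold there. Camera with the preset correlation called the shifted list and 0 of 28 unchanged lists, in data simulated without correlation between genes.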

Results

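RNA from 4 obstructed and 4 unobstructed mouse kidneys was compared 24 h after ureteral obstruction, to follow the genes controlled by HNF1B (hepatocyte nuclear factor 1 beta), a transcription factor of the kidney tubule, at an early stage of kidney damage. The libraries held 20.2 ± 3.25 M reads in UUO and 21.7 ± 1.30 M reads in CTRL (exact permutation p = 0.429, two-sided). The smallest p such a test can give for 4 against 4 is 0.0286. Replicates within a group correlated with Spearman's rho of 0.992 to 0.996 across genes, against 0.948 to 0.962 between groups, where genes are not independent replicates. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 5.92 to 17.7). The first principal component held 78.6% of the variance and separated the groups.

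Obstruction was accompanied by a rise of injury, cytokine and acute phase genes and a fall of most transport genes in the tubule segments examined. Of 16669 genes tested, 4971 were higher and 4957 lower in UUO (limma, adjusted p under the threshold of 0.05), 59.6% of the genes. At least 2-fold changes were found for 1182 genes upwards and 1345 downwards. In 54.1% of the genes the ranges of the groups did not overlap, where chance gives 2.86%. Of the genes past the threshold 50.1% were higher. That share was 61.2% when the libraries were rescaled to equal sums, because the deposited values summed to 20.4 ± 0.510 M in UUO and 21.9 ± 0.274 M in CTRL (exact permutation p = 0.0286), and this rescaling moved the median change of all genes from 0.003 to 0.11 on the log2 scale. edgeR on the recovered reads called 5082 genes higher and 4860 lower, of which 9804 were also called by limma in the same direction.

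Hnf1b itself (chromosome 11, 83850063 to 83905819, GRCm38, plus strand) was measured at 5110 ± 404 normalised reads in CTRL and 4978 ± 373 in UUO. Its log2 fold change was -0.037 (SE 0.075, 95% interval -0.20 to 0.13, limma adjusted p = 0.691), less than the spread between replicates, and its sign turned, to 0.069, after rescaling to equal sums. Hnf4a, a nuclear receptor of the proximal tubule (chromosome 2, 163506808 to 163572910), fell from 23585 ± 942 to 11437 ± 1897 (log2 fold change -1.06, SE 0.112, adjusted p = 7.91e-06). Hnf1a, the close relative of Hnf1b that is expressed in the proximal tubule (chromosome 5, 114948980 to 114971094), fell from 2340 ± 120 to 1106 ± 161 (log2 fold change -1.09, SE 0.098, adjusted p = 2.16e-06). A gene on the opposite strand overlaps 26.6% of the exonic bases of Hnf1a, so its level is less certain.

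The list of HNF1B-dependent genes was drawn from general knowledge. Of its 27 genes, all measured, 21 fell, 2 rose and 4 did not pass the test. Adjusted over the list alone, 21 fell and 3 rose. The median log2 fold change was -0.61. Pde4c, a cyclic AMP phosphodiesterase, fell from 2634 ± 161 to 818 ± 41.9 (log2 fold change -1.68). Pkd2, a gene of polycystic kidney disease, fell by 0.98 on the log2 scale, Umod, which encodes uromodulin, by 0.88, and Cdh16, the kidney-specific cadherin, by 0.79. Ppargc1a, a regulator of mitochondrial genes, fell by 1.42. Socs3, an inhibitor of cytokine signalling that is also in the STAT3 and acute phase list, rose from 396 ± 62.0 to 3776 ± 883 (log2 fold change 3.23). Bicc1, an RNA-binding protein, rose by 0.71. The list was fixed without a direction for each member. Neither these rises nor the falls therefore count for or against HNF1B dependence. Pkhd1, the gene of recessive polycystic kidney disease, was at 6348 ± 738 and 6564 ± 763, with a change of 0.05 that turned to -0.03 without CTRL sample 2 and to -0.02 without UUO sample 1. Camera placed the list below other genes (adjusted p = 2.21e-05) with the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.0573). The estimated correlation of this list was 0.0018, below the preset value. A stronger correlation between its genes than the preset one therefore does not account for the loss. Of the 27 members, 10 belong to another list too, and the 17 others had a median of -0.54, with 13 lower and 1 higher.

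**Figure D1:**
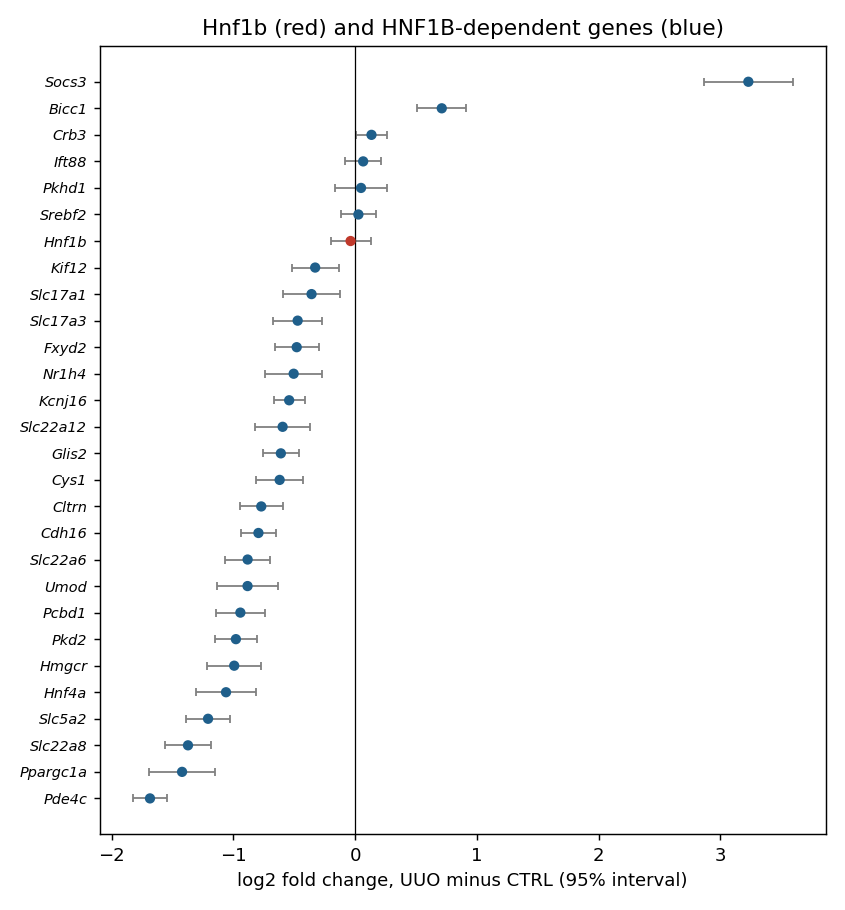
Log2 fold changes (UUO minus CTRL, 4 kidneys each) of Hnf1b (red) and the 27 HNF1B-dependent genes (blue), with bars for 95% intervals. Hnf1b lies at -0.037, 21 genes fell, and Socs3 and Bicc1 rose.

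All 20 measured genes of tubular injury rose, with a median log2 fold change of 2.82 (camera adjusted p = 3.79e-14, adjusted p = 0.0573 with an estimated correlation). Clu, the chaperone clusterin, rose from 6501 ± 892 to 58068 ± 2633, and Krt20, a keratin of simple epithelia, from 20.1 ± 7.21 to 2267 ± 592. Lcn2, which encodes the urinary injury marker NGAL and was chosen after its values were seen, rose from 298 ± 133 to 12118 ± 1889. Havcr1, which encodes kidney injury molecule 1 (chromosome 11, 46735080 to 46779578), was at 8548 to 20100 in UUO and at 7.57 to 13.9 in 3 CTRL samples, but at 2360 in CTRL sample 4. Its log2 fold change was 8.10 (SE 1.42, adjusted p = 0.00042) and 10.03 (SE 0.260) without that sample, while edgeR gave 4.39.

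Of the 10 largest rises under the naming rule, 5 had at most 2 reads over all CTRL libraries. Vgf, a secreted neuropeptide precursor, had no read in any CTRL library and 424 ± 152 normalised reads in UUO, at least 139-fold higher against a floor of 3 reads per library. For Sprr2f, a cornified envelope gene with close paralogs that make its level uncertain, 2 reads over all CTRL libraries stood against 2045 in UUO, a ratio of 1014 (95% counting interval 280.3 to 8377). Saa1, an acute phase protein with close paralogs, had 2 reads against 1403, a ratio of 696 (192 to 5749). The interleukin 1 family cytokine Il1f6 had 1 read against 1144 (ratio 1134, interval 203 to 44838) and the chemokine Ccl20 had 1 against 903 (ratio 895, interval 160.3 to 35401).

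All 24 cytokine and NF-kB genes rose (median 3.31, camera adjusted p = 3.79e-14, adjusted p = 0.0637 with an estimated correlation). The cytokine Il11 rose from 6.65 ± 2.99 to 708 ± 105, Lif from 13.8 ± 2.33 to 1438 ± 591, and the NF-kB subunit Relb from 178 ± 14.4 to 853 ± 67.7. All 14 genes of STAT3 signalling and the acute phase rose as well (median 2.51, camera adjusted p = 3.81e-09, adjusted p = 0.0899 with an estimated correlation). The 3 fibrinogen chains were among them. Fga rose from 782 ± 130 to 33559 ± 6856, Fgb from 91.6 ± 13.6 to 13897 ± 3951 and Fgg from 319 ± 60.7 to 21029 ± 5414.

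Of 17 measured immediate early genes 13 rose and 1 fell (median 1.59, camera adjusted p = 6.54e-06, adjusted p = 0.193 with an estimated correlation). Leaving out CTRL sample 4 moved the median to 1.06. Myc and Maff rose by log2 fold changes of 3.08 and 3.25, and Fosl1 by 3.15, although 57.2% of its exonic bases overlap a gene on the other strand. Dusp1, a phosphatase of MAP kinases, fell by 0.72 (adjusted p = 0.0214), a call that was lost without CTRL sample 1 (adjusted p = 0.0569), without CTRL sample 2 (adjusted p = 0.0561) or without UUO sample 4 (adjusted p = 0.0531), and with robust variances (adjusted p = 0.0674). Among 21 matrix and TGF-beta genes 18 rose and 2 fell (median 1.18, camera adjusted p = 4.08e-08, adjusted p = 0.136 with an estimated correlation). Serpine1, an inhibitor of plasminogen activation, rose from 117 ± 24.7 to 1881 ± 222 and the matrix protein Tnc from 336 ± 120 to 3730 ± 465. Tgfb1 rose by 1.71 and Tgfb2 was lower by a log2 fold change of -0.27 (adjusted p = 0.0432). The Tgfb2 call was lost without CTRL sample 2, 3 or 4 or any single UUO sample other than UUO sample 3 (adjusted p up to 0.121), and with edgeR (0.0577 adjusted p) or DESeq2 (0.0582 adjusted p) on the recovered reads.

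Of 23 cell cycle genes 14 rose and 1 fell (median 0.67, camera adjusted p = 0.00101, adjusted p = 0.457 with an estimated correlation). Ccne1 rose from 18.5 ± 1.57 to 76.6 ± 8.36, Mcm7 by 0.89 and Pcna by 0.67 on the log2 scale. Ccnd1, a cyclin of the G1 phase, fell by 1.09. Of 15 p53 targets 9 rose and 1 fell (median 0.89, camera adjusted p = 0.00101, adjusted p = 0.137 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 309 ± 41.9 to 1691 ± 178, the stress cytokine Gdf15 from 181 ± 52.6 to 2358 ± 717, and Ccng1 fell by 0.47.

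**Figure D2:**
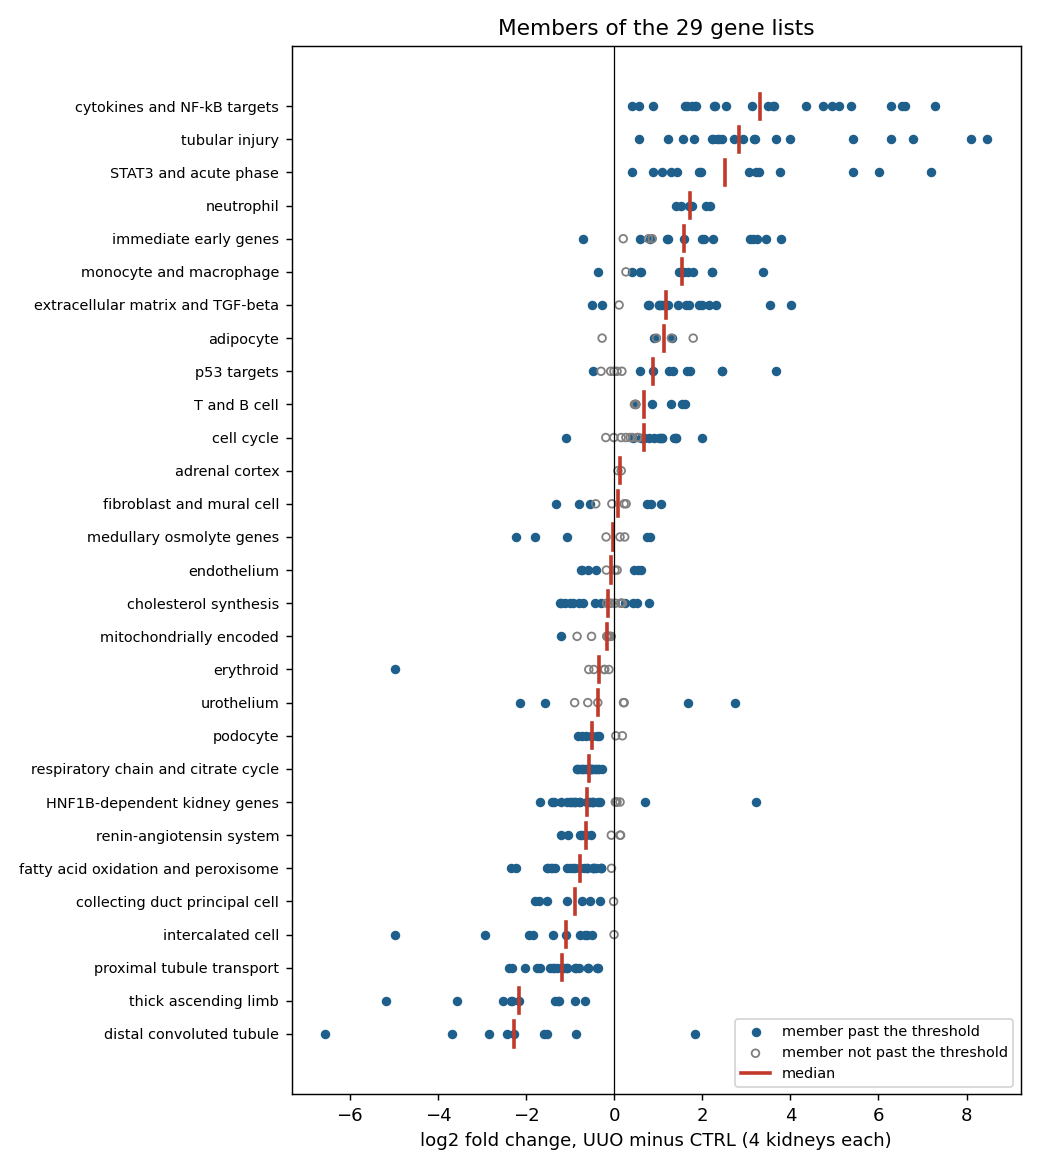
Log2 fold changes (UUO minus CTRL, 4 kidneys each) of the measured members of 29 gene lists; filled points passed the threshold, open points did not, and red bars mark medians. The medians run from -2.27 for the distal convoluted tubule to 3.31 for cytokines and NF-kB targets.

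The transport genes of the proximal tubule, which reclaims most filtered solutes, fell in all 20 cases (median -1.17, camera adjusted p = 5.35e-09, adjusted p = 0.0573 with an estimated correlation). The phosphate transporter Slc34a1 fell from 85282 ± 2341 to 25509 ± 1943, the lactate transporter Slc5a12 by 2.38 on the log2 scale, and the organic anion transporter Slc22a8 by 1.37. Of 23 genes of fatty acid oxidation and peroxisomes 22 fell (median -0.78, camera adjusted p = 1.14e-08, adjusted p = 0.136 with an estimated correlation), among them Acsm2 by 2.24, Acaa2 by 1.44 and Ehhadh by 1.07. All 21 genes of the respiratory chain and citrate cycle fell (median -0.56, camera adjusted p = 1.14e-08, adjusted p = 0.193 with an estimated correlation), including Aco2, the mitochondrial aconitase, by 0.85 and Ndufs1, a subunit of complex I, by 0.83. Of the 9 mitochondrially encoded genes 1 fell, mt-Co2 by 1.20, and the list was not called (median -0.16, camera adjusted p = 0.228).

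Pvalb, a calcium-binding protein of the distal convoluted tubule, went from 583 ± 247 to 7.12 ± 8.48. Egf, made by the thick ascending limb and early distal tubule (chromosome 3, 129677565 to 129755316), fell from 25511 ± 2184 to 719 ± 186 (log2 fold change -5.18, SE 0.145, adjusted p = 1.12e-09). The chloride-bicarbonate exchanger Slc4a1 fell from 1087 ± 45.6 to 36.8 ± 17.4, the proton pump Atp4a from 1455 ± 85.4 to 91.4 ± 12.9, the potassium channel Kcnt1 from 670.1 ± 133 to 27.4 ± 7.04, and G6pc, the glucose-releasing phosphatase of gluconeogenesis, from 10415 ± 2432 to 701 ± 143. Nccrp1, Mfrp, Ppp1r1b and Car14 complete the 10 largest falls under the naming rule, with log2 fold changes from -5.19 to -3.91. Mfrp shares 36.7% of its exonic bases with a gene on the same strand and is uncertain.

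All 11 genes of the thick ascending limb fell (median -2.16, camera adjusted p = 4.08e-08, adjusted p = 0.131 with an estimated correlation), among them the potassium channel Kcnj1 by 2.33 and the chloride channel Clcnkb by 1.34. In the distal convoluted tubule 8 of 9 genes fell (median -2.27, camera adjusted p = 0.000108, adjusted p = 0.136 with an estimated correlation). The calcium buffer Calb1 fell by 3.69 and the thiazide-sensitive cotransporter Slc12a3 by 1.52, whereas the calcium channel Trpv5 rose from 766 ± 82.1 to 2748 ± 376. Principal cells of the collecting duct had 7 of 8 genes lower (median -0.89, camera adjusted p = 0.000729, adjusted p = 0.176 with an estimated correlation), with the water channel Aqp3 down by a log2 fold change of -1.80. Intercalated cells had 10 of 11 lower (median -1.10, camera adjusted p = 6.54e-06, adjusted p = 0.136 with an estimated correlation), with the proton pump subunit Atp6v1b1 at -1.93 and pendrin, Slc26a4, at -1.39.

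Of 9 measured genes of the renin-angiotensin system 6 fell (median -0.65, camera adjusted p = 0.00492, adjusted p = 0.0899 with an estimated correlation), including the receptor Agtr1a by 1.05 and the peptidase Mme by 0.77. Of 9 podocyte genes 7 fell (median -0.50, camera adjusted p = 0.0283, adjusted p = 0.441 with an estimated correlation), with Nphs2 down by 0.73 and Podxl by 0.63. Without UUO sample 2 the podocyte list was no longer called (adjusted p = 0.0575), nor with edgeR (adjusted p = 0.0787) or DESeq2 (adjusted p = 0.0864) on the recovered reads.

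Of 12 monocyte and macrophage genes 10 rose and 1 fell (median 1.54, camera adjusted p = 0.000153, adjusted p = 0.0899 with an estimated correlation). The chemokine receptor Ccr2 rose from 52.1 ± 3.34 to 185 ± 25.6 and Cd14 from 161 ± 20.1 to 1743 ± 543, while Csf1r, the receptor of resident macrophages and monocytes alike, fell by 0.37. All 6 measured neutrophil genes of 10 rose (median 1.73, camera adjusted p = 0.00473, adjusted p = 0.148 with an estimated correlation), among them Csf3r from 40.7 ± 9.75 to 133 ± 23.7, and the call was lost with a minimum mean of 50 (adjusted p = 0.121). Of 8 measured T and B cell genes 5 rose (median 0.67, camera adjusted p = 0.0367, adjusted p = 0.136 with an estimated correlation), at low levels: Cd79a was at 5.58 ± 0.689 and 19.1 ± 3.19. That call was lost when CTRL sample 4 or any UUO sample was left out (adjusted p from 0.0506 to 0.268), and the median was 0.39 without UUO sample 2. With edgeR on the recovered reads its adjusted p was 0.176.

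The remaining lists were not called by camera with limma at the preset correlation. Among them fry passed, downwards, for cholesterol synthesis (fry adjusted p = 0.0018), medullary osmolyte genes (0.0391) and the erythroid list (0.0422). Cholesterol synthesis had 4 genes higher and 9 lower (median -0.14, camera adjusted p = 0.108), and was called lower with no filter (adjusted p = 0.0308), edgeR (0.0438) and DESeq2 (0.0380), with Mvd at -1.23 and Stard4 at -1.12. Medullary osmolyte genes had 2 higher and 3 lower (median -0.02, adjusted p = 0.652), with the betaine transporter Slc6a12 at -2.22. Endothelial genes divided into 3 higher, such as Cdh5 at 0.60, and 4 lower, such as Ehd3 at -0.75 (adjusted p = 0.870). Fibroblast and mural cell genes divided into 3 and 3, with Pdgfrb at 0.84 and Myh11 at -0.80; their median was 0.09 while camera pointed down (adjusted p = 0.898). Urothelial genes divided into the keratins Krt14 and Krt5 upwards and 2 uroplakins downwards (adjusted p = 0.987), with Krt14 at 2.74 and Upk3a at -2.15. Adipocyte genes had 2 of 6 higher (adjusted p = 0.215) and the 2 measured adrenal genes did not pass (adjusted p = 0.832). The erythroid list (adjusted p = 0.169), of which Slc4a1 is also an intercalated cell gene, was called lower with edgeR (0.0360) and DESeq2 (0.0378). Its member Hba-a1 was at 1324 ± 352 and 971 ± 301 (limma adjusted p = 0.106), and passed with sample quality weights (0.0335), without CTRL sample 2 (0.0243) and without UUO sample 1 (0.0315). Alas2 (0.0881) passed in the same 3 ways (0.0313, 0.0072 and 0.0439) and with DESeq2 (0.0314).

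Camera called 10 of 29 higher and 10 lower with the preset correlation and 0 with an estimated correlation. The estimate was below the preset value for the HNF1B-dependent (0.0018), renin-angiotensin (-0.032) and T and B cell (-0.038) lists. A stronger correlation between genes does not account for their lost calls, and what does was not tested. The other called lists had estimates above the preset value, from 0.057 (monocytes and macrophages) to 0.61 (respiratory chain and citrate cycle). Fry passed for every list called with the preset correlation, in the same direction (adjusted p up to 0.0042, for podocyte genes), but compares with no other genes. The counts of single genes given above only describe the lists. They were not compared with the 59.6% of all tested genes that passed the threshold, and cannot replace a list test.

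**Figure D3:**
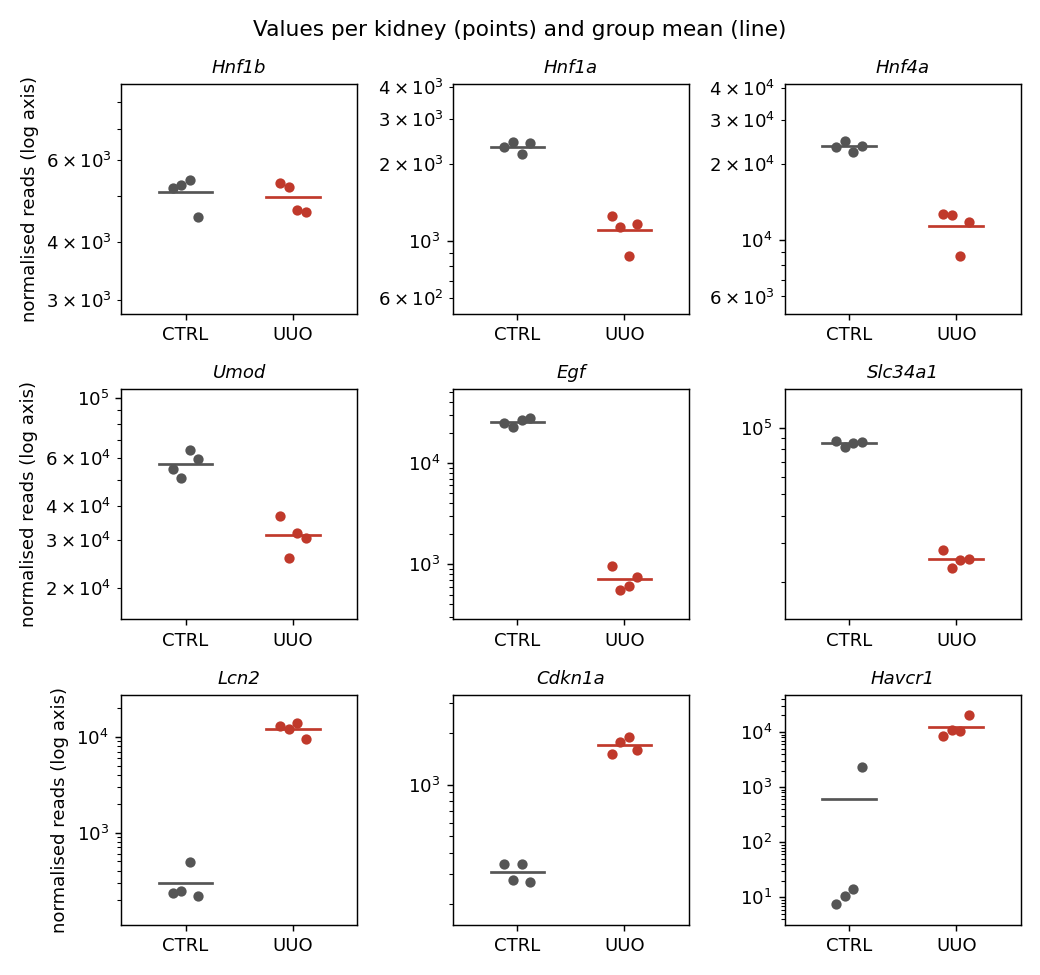
Normalised reads of 9 genes in each kidney (points, log axes that do not start at 0) with group means (lines) for 4 CTRL and 4 UUO kidneys. Hnf1b overlaps between the groups, and Havcr1 in CTRL sample 4 (2360) lies apart from the other CTRL samples.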

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

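The splits of the samples were planned before their results were seen; the tests of carry-over, of chromosomal position and of the HNF1B-dependent genes were chosen after the patterns were seen. Of 223 groups of 4 kidneys checked for a sample far from the others (total reads, Xist and the genes named in the report), 7 had one, where chance gives about 1 in 20. CTRL samples stood apart in single genes. Havcr1 was at 2360 in CTRL sample 4, Lcn2 at 496 in CTRL sample 3 (215 to 248 in the others), Kcnj1 at 7026 in CTRL sample 4 (7769 to 7913) and Star at 93.02 in CTRL sample 1 (117 to 118). Saa1 at 1.94 in CTRL sample 4, Il1f6 at 0.943 in CTRL sample 2 and Ccl20 at 1.07 in CTRL sample 3 rest on 1 or 2 reads. A further 3 genes were picked because they set CTRL sample 4 and UUO sample 4 apart. For 2 of them both kidneys stood apart: Pttg1 was at 66.0 and 41.9 in these kidneys (652 to 850 in the other CTRL and 439 to 504 in the other UUO samples), and Glo1 at 5072 and 4462 (1834 to 1940 and 1587 to 1865).

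Havcr1 was part of a wider pattern: in CTRL sample 4 and UUO sample 4, 39 genes with a mean value of at least 50 deviated by at least 1 (log2) in the same direction from the other samples of their group, against at most 15 in the other 15 pairs of a CTRL and a UUO sample. Carry-over of RNA from obstructed kidneys would need a share of 18.8% to account for Havcr1, but over 28 other genes nearly silent in CTRL the median implied share was -0.163% (upper quartile 0.151%), which argues against it. Inherited sequence differences, for instance if both kidneys came from 1 mouse, may account for some of the 39 genes and stay open. Of the 39, 16 had another member within 10 Mb. That lies between the median of 12 and the 95th percentile of 18 over 10000 random gene sets (permutation p = 0.159). A bound first set at that percentile would have counted against inherited differences. It was relaxed to the median after the result was seen, since unlinked differences need no neighbours. On chromosome 11 between 40 and 60 Mb lay 7 of the 39, Havcr1 and Pttg1 among them. That window holds 149 of the 13292 genes from which the random sets were drawn. It was chosen after looking, so the count is no test of clustering. Whether 1 cause lies behind all 39 was not tested. They also include the immediate early genes Fos and Egr1, which were lower in CTRL sample 4 (-2.80 and -2.18) and UUO sample 4 (-1.02 and -1.10).

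Of 27 HNF1B-dependent genes 21 fell, 2 rose and 4 did not pass, while Hnf1b mRNA passed no threshold. The call of the list was lost with an estimated correlation (adjusted p = 0.0573), although that correlation was 0.0018, below the preset value. Less Hnf1b mRNA is argued against by its log2 fold change of -0.037, whose 95% interval ends at -0.20, while the median of the list was -0.61. An equal loss of cells from all tubule segments is argued against as the whole account. The thick ascending limb list fell further than the proximal tubule list by -0.95 (log2, exact permutation p = 0.0286, the smallest possible). A lower share of tubule cells through a loss that differs between segments stays open. Shared members with other lists are argued against as the whole account by a median of -0.54 over the members in no other list. That value cannot separate HNF1B dependence from a fall of tubule genes in general. The lists of the tubule segments fell further: medians were -1.17 (proximal tubule), -2.16 (thick ascending limb), -2.27 (distal convoluted tubule), -0.89 (principal cells) and -1.10 (intercalated cells). HNF1B protein and its binding to these genes were not measured, so lower HNF1B activity may contribute and remains an untested hypothesis. Hnf1a and Hnf4a mRNA fell, by log2 fold changes of -1.09 and -1.06. Whether their fall accounts for that of the list was not tested either. Without Hnf4a and the proximal tubule members the list median was -0.54 (camera adjusted p = 0.0011), which does not settle it.

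For the gene counts the real split of the samples stood alone, but 1 of 35 is the smallest share such splits can give. The other splits mix the groups, so the difference between UUO and CTRL widens their spread and leaves few calls. The splits therefore cannot exclude chance for the gene counts, and they left it open for the count of gene lists. Only 1 of the 35 splits of the 8 samples into 4 and 4, the real split, gave 9928 genes past the threshold, and the highest of the others gave 1 gene. The same held for genes at least 2-fold apart (2527 against 1). For the lists called by camera, however, 8 of the 35 splits gave at least the 20 of the real split, and the highest other gave 22. The other splits with at least 20 lists all kept 3 kidneys of each group together and so retained part of the real contrast, which makes them no reference without an effect. The 16 splits of this kind called 15 to 22 lists, and the 18 that divided both groups evenly called 0 to 6. For the HNF1B-dependent list 1 of 35 splits gave so small an adjusted p, with a negative log10 of 4.66 against 4.49 in the highest other, which also kept 3 kidneys of each group together.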

How the results depend on the processing

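The counts of genes higher and lower in UUO stayed within 1.5 times under every alternative run, with each library left out in turn (4438 to 4820 higher, 4420 to 4848 lower) and, as chosen after seeing the data, without CTRL sample 4 and UUO sample 4 (4154 higher, 4182 lower). With a minimum mean of 50, 766 genes were at least 2-fold higher, as fewer genes were tested (13311). Rescaling to equal sums turned the log2 change of Hnf1b to 0.069 and the list medians of medullary osmolyte genes to 0.083 and endothelium to 0.028, a shift set by the rescaling itself; Hnf1b passed no threshold under any alternative (-0.095 to -0.0038 with single libraries left out). With an estimated correlation 0 lists were called higher and 0 lower, and the HNF1B-dependent list, at -0.61, had an adjusted p of 0.0573. Across its other alternatives that p ran from 3.53e-08 to 0.0011. The fibroblast and mural cell median was -0.051 with the minimum mean of 50 and ran from -0.092 to 0.19 with single libraries left out. Medullary osmolyte genes ran from -0.094 to 0.052 and Pkhd1 from -0.028 to 0.11 in the same way, and the cause was not tested. Of 1415 values of named genes under the alternatives 1401 kept direction and side of the threshold, 8 lost a call (Tgfb2 and Dusp1), 5 gained one (Alas2 and Hba-a1) and 1 changed sign. With single libraries left out, 832 of 848 kept both. The title numbers of the kidneys, 21 apart in each pair, are not said to mark mice. Kidneys paired in this way had correlations of their deviations of 0.129, 0.326, 0.055 and 0.442, and 5 of the 8 correlated best with their own partner, a hint from the data and not the design. With these pairs as a block, added after the data were seen, 5317 genes were higher and 5327 lower, 10 lists were called higher and 11 lower, and the erythroid list (adjusted p = 0.0231), Hba-a1 (4.2e-05) and Alas2 (0.00085) gained a call. Depth limits the genes with few reads: a gene with no CTRL read allows only a lower bound on its fold.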

Other observations

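The tests of sex-linked genes and of the gene families were chosen after the values were seen. In 10 families picked from the table and matched by gene symbol alone, ribosomal protein genes were mostly higher (76 of 81 rose and 1 fell, median log2 fold change 0.44, camera adjusted p = 6.45e-10, adjusted p = 0.356 with an estimated correlation), as were Psm genes, which include assembly factors of the proteasome (34 of 46 rose, 2 fell), and Eif genes, which include kinases and repressors of translation initiation (35 of 53 rose, 5 fell). Genes with interferon-related symbols had 21 of 28 higher and 2 lower, and keratins 10 of 14 higher and 1 lower. Lower were Slc22a genes (21 of 23 fell, 1 rose), Nduf genes (27 of 36 fell, 0 rose), cytochromes P450 (30 of 45 fell, 10 rose), Kcn genes of potassium channels (27 of 47 fell, 4 rose) and histones (9 of 12 fell, 0 rose). None of the 10 passed with an estimated correlation (adjusted p from 0.0511 to 0.356).

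By class of transcript, 35 of 346 lincRNA genes rose and 141 fell, and 38 of 433 antisense genes rose and 169 fell, whereas 232 of 797 processed pseudogenes rose and 63 fell. As the strand setting is not given, antisense genes cannot be taken as separated from their partners, and processed pseudogenes share sequence with their parent genes.

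The labels describe male mice, yet all 8 libraries held Xist, the RNA that silences an X chromosome in females, at 15383 ± 989 normalised reads (SD, 8 libraries), and no read in Ddx3y, Uty, Kdm5d or Eif2s3y, which are expressed from the Y chromosome. Loss of Y reads in alignment or counting would leave Xist near 0 in males, but its lowest value was 14272. Tsix, the antisense partner of Xist, averaged 0.786. A single mixed-up library is argued against because 8 of 8 libraries showed the pattern. The X-linked counterparts of these Y genes averaged from 1204 (Kdm6a) to 8408 (Ddx3x). Together these values argue against male mice for all 8 libraries. Female animals, and so a wrong sex in the labels, would account for the pattern.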
